A study of Caenorhabditis elegans with 18 samples.

How the data were processed

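Ribosome profiling (Ribo-seq) sequences the stretches of mRNA that a ribosome shields from nuclease, so that the number of footprint reads on a gene reflects both its mRNA level and how heavily that mRNA is translated. Per the labels' protocols, synchronised Caenorhabditis elegans were grown for 45 hours after feeding and lysed in cycloheximide. The lysate was digested with RNase I, monosomes were taken from a sucrose gradient, and RNA close to the size of a ribosome footprint was cut from a gel. The labels describe 18 samples in 6 groups of 3: wild type, a null allele of alg-1, and the alleles F180del, G199S, V254I and H751L. The series also names RNA-seq, which was not used here, so translational efficiency was not computed.

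The deposited values are whole-number counts of reads per gene with no normalization, 1 column per library. Per the submitters' processing notes, the tools were cutadapt 1.9 and Bowtie2 2.3.5.1, named without role or order. The read counter, genome build, annotation, footprint length filter and treatment of reads that match several genes are not given in the sources used here. The last of these affects histones, actins, vitellogenins, major sperm proteins and other families with near-identical members, whose values are uncertain gene by gene. Totals over such families would be too high if a shared read was counted for every copy.

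Columns were joined to groups by name only. The wild-type columns carry the strain name N2, which the labels give as the genotype of the wild-type group alone. The other 15 columns carry 5 strain names that match no label, and no pairing of strain with allele was assumed, so those columns entered no step. The 3 wild-type columns end in the letters A, B and C, which do not say which labelled replicate each is; they are called libraries A, B and C. Nothing in the labels says whether replicates came from separate cultures, so the spread between libraries may be technical.

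All 24 tests fixed before the data were examined compare an alg-1 allele with wild type, with the null or with other alleles, and none was run. The rule for named genes, fixed with them, selects genes by those tests and always includes alg-1 and alg-2. It was replaced, after the data were examined, by the 20 genes with the highest mean, the 4 most abundant members of each gene list, and a hand-picked set of genes from the heterochronic, microRNA, germline and collagen groups, some of them picked after their values were seen. The 24 gene lists themselves were fixed before the data were examined. Every other choice described here, and every alternative setting, was made afterwards.

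The table has 46727 gene rows, of which 19793 had no gene name. Names for 18646 of these were taken by sequence name from a RefSeq table of assembly WBcel235, used for names only. A further 272 rows have no sequence name. The lists found 1421 memberships in the file, and 6 names were not found.

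Counts were divided by the library total and scaled to the unit CPM, with the mean and SD over 3 libraries. The library totals were 9121493, 10273375 and 2759428 counts for A, B and C. A limit of 3 counts, the most that a count of 0 allows, corresponds to 0.329, 0.292 and 1.09 CPM. It covers counting error only. A gene was called detected at 1 CPM or more in every library, and genes with at least 10 counts in every library were compared between libraries.

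The spread between libraries was estimated with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default filter on low counts and a common dispersion, given as the biological coefficient of variation. The steps were tested on simulated data for these wild-type libraries, with 11440 genes, 200 of them changed and drawn from the more abundant ones. A log2 difference of -1 in 1 library was recovered as a median of -0.96. With the changed genes left out, a coefficient of 14.2% was recovered as 14.1%. How changed genes alter the coefficient was not tested.

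For each gene, the log2 CPM of a library was set against the mean log2 CPM of the other libraries, and the median of all compared genes was subtracted. A list with at least 5 compared members was summarised by its median. That median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries and not of a condition. Its 95% interval came from resampling the members. The 3 differences of a gene sum to 0 before centring, so they are not independent of one another. Alternatives were TMM scaling, thinning to the smallest total, removal of the 20 most abundant genes, 1 row per set of genes with equal counts, protein-coding rows only, other count filters, RLE in place of TMM, and each library left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.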

Results

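The series was designed to compare translation in worms that carry alleles of alg-1, a microRNA Argonaute, with that in wild type and in an alg-1 null. The 4 alleles model changes in human AGO1 found in neurodevelopmental disorders. Only the 3 wild-type libraries could be tied to a labelled group, so the values below describe wild-type whole animals at 45 hours after feeding, and no comparison between genotypes was made. Libraries A and B held 9121493 and 10273375 counts and library C held 2759428, so values for rare genes are least precise in C. Of 46727 gene rows, 11708 were detected in all 3 libraries, and 15652, 15691 and 14391 rows had at least 1 count in A, B and C.

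The first question is which genes held the most footprint reads. Counts were not divided by gene length, so long genes rank higher at the same density of ribosomes. The elongation factor gene eef-1A.1 had the highest level, 22186 ± 255 CPM (SD, n = 3). It was followed by bcf-1 at 9196 ± 854 CPM and gfi-1 at 8799 ± 770 CPM. Their counts ran close in every library, 75986 and 72907 in A, 94705 and 91202 in B, and 27700 and 26291 in C. Whether bcf-1 and gfi-1 share reads was not tested, so they may not be separate measurements. The actin genes act-3 and act-1 stood at 8198 ± 353 and 8125 ± 381 CPM, elongation factor eef-2 at 8076 ± 778 CPM, and unc-54, the major body wall myosin heavy chain, at 7093 ± 1301 CPM. Actins are near-identical in sequence, so the split between act-1, act-2, act-3 and act-4 is uncertain. The 20 most abundant genes took 11.8%, 11.9% and 12.8% of counts in A, B and C. Protein-coding rows took 99.7% ± 0.0134 (SD, n = 3). Rows of 8 types, 16850 in number and including piRNA, microRNA, tRNA and rRNA genes, were listed at 0 in all 3 libraries. Whether reads of these types were removed or left uncounted is not given. The zeros and the protein-coding share therefore do not describe what the libraries held.

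Among the fixed gene lists, ribosomal proteins held the largest share, 8.25% ± 0.350 (SD, n = 3), with 81 of 83 members detected. Cuticle collagens, the structural proteins of the worm's exoskeleton, followed at 7.08% ± 1.51 with 140 of 179 detected. Translation factors held 4.64% ± 0.166 and histones 2.82% ± 0.497. Without the 20 most abundant genes, translation factors fell from 46367 to 14744 CPM. Totals of families with near-identical members, such as histones and some collagens, would be too high if shared reads were counted for every copy. Body wall muscle markers held 2.38% ± 0.281, nuclear genes of oxidative phosphorylation 1.80% ± 0.0239, and heat shock and unfolded protein response genes 1.75% ± 0.0662. At the low end, neuronal markers held 0.0408% ± 0.00454 and neuropeptides 0.0343% ± 0.00407. Pharynx markers held 0.0584% ± 0.00923. Immune and antimicrobial genes held 0.723% ± 0.0247, detoxification genes 0.510% ± 0.00281, lipid metabolism genes 1.05% ± 0.0406 and intestine markers 1.35% ± 0.144.

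**Figure D1:**
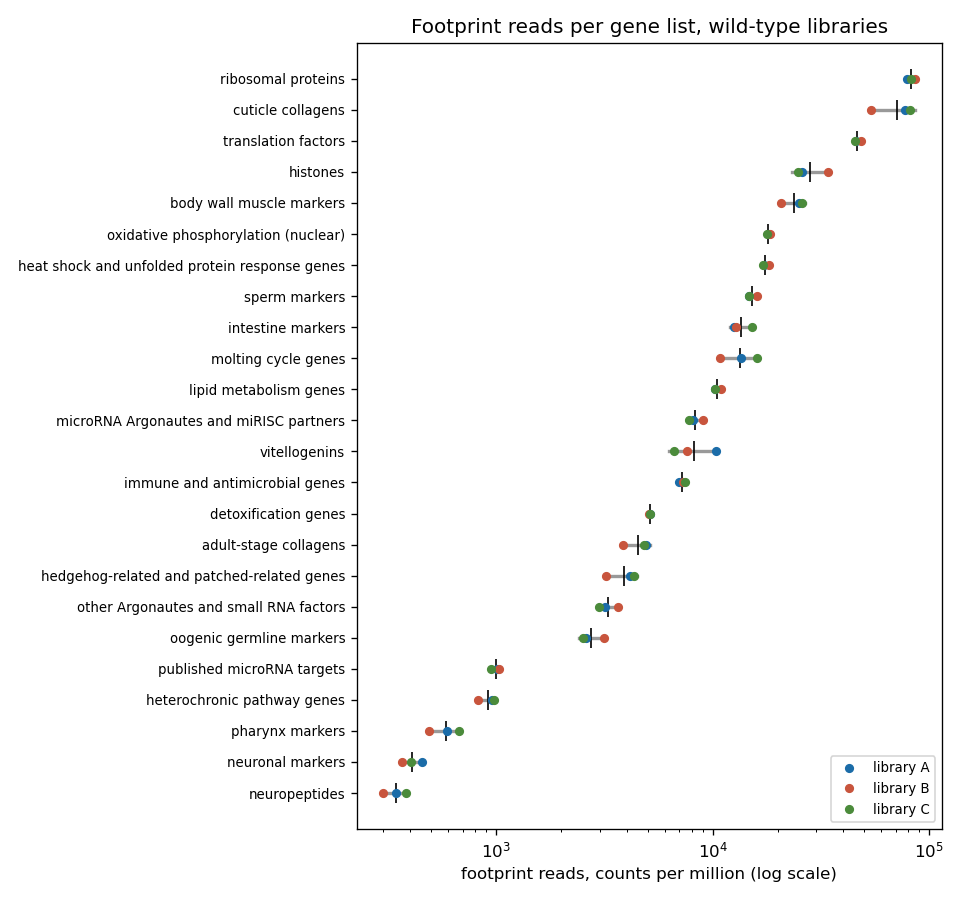
Footprint reads in each gene list in CPM on a log axis. Points are libraries A, B and C, the black tick is their mean and the grey bar 1 SD to either side (n = 3); ribosomal proteins are highest at 82549 CPM and neuropeptides lowest at 343 CPM.

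The second question is the level of alg-1 and the microRNA machinery in wild type, the baseline of the study. The alg-1 gene stood at 59 ± 7.44 CPM (SD, n = 3), from 516, 546 and 186 counts in A, B and C. Its paralog alg-2 stood at 47.2 ± 2.84 CPM, from 455, 487 and 122 counts. The ratio of alg-1 to alg-2 was 1.13, 1.12 and 1.52, above 1 in 3 of 3 libraries, with a mean of 1.26 ± 0.229. These are counts not divided by gene length, and how reads shared by the paralogs were counted is not given. The third microRNA Argonaute, alg-5, stood at 14.9 ± 3.26 CPM. The GW182-type cofactors ain-1 and ain-2 stood at 77.5 ± 2.28 and 61.6 ± 11.1 CPM. All 28 microRNA Argonautes and miRISC partners in the file were detected and together held 0.828% ± 0.0670 of counts, with vig-1 highest at 2162 ± 277 CPM and cgh-1, a DEAD-box RNA helicase, at 1247 ± 17.9 CPM. All 26 other Argonautes and small RNA factors were detected too, at 0.327% ± 0.0342, with csr-1 at 726 ± 89.4 and wago-1 at 609 ± 69.6 CPM.

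Heterochronic genes, which set the timing of larval cell fates and include direct microRNA targets, held 0.0918% ± 0.00827 of counts with 17 of 18 detected. lin-41, a target of let-7, stood at 40.9 ± 4.04 CPM, and lin-14, a target of lin-4, at 8.25 ± 0.298 CPM. The ratio of lin-41 to lin-14 was 4.97 ± 0.581, from 4.35 to 5.51 over the libraries. Here too counts were not divided by gene length, so the ratio may partly reflect length. lin-28 stood at 13.4 ± 3.76 CPM, lin-42 at 36.9 ± 4.29 CPM, daf-12 at 8.52 ± 1.21 CPM and let-60 at 37.8 ± 3.48 CPM. Levels near the detection limit were found for hbl-1, at 1.89 ± 0.277 CPM from 20, 17 and 5 counts, and for lin-46, at 1.14 ± 0.289 CPM from 10, 9 and 4 counts. lin-29, which acts at the larval-to-adult switch, stood at 5.78 ± 1.69 CPM and its cofactor mab-10 at 5.96 ± 2.00 CPM. The 32 published microRNA targets held 0.0994% ± 0.00464, with 30 detected.

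Stage and tissue genes were present at unlike levels. The most abundant cuticle collagens were col-3 and col-117, at 3220 ± 653 CPM each, dpy-5, at 2965 ± 768 CPM, and col-10, at 2867 ± 695 CPM. The counts of col-3 and col-117 differed by 36, 19 and 7 in A, B and C, closer than a random split of their reads (SD 251, 226 and 143), so they are not separate measurements. The adult-stage collagens together held 0.453% ± 0.0596 with 8 of 8 detected. Among them col-38 was highest at 2345 ± 374 CPM, while col-19 stood at 86.6 ± 27.6 CPM and col-7 at 64.1 ± 36.3 CPM. Sperm markers held 1.51% ± 0.0738 with 90 of 105 detected, among them the major sperm protein gene msp-79 at 690 ± 35.0 CPM. Oogenic germline markers held 0.274% ± 0.0338 with 30 of 34 detected. Within that list the P granule genes glh-1 and pgl-1 stood at 735 ± 101 and 476 ± 88.4 CPM. The oocyte genes oma-1 and rme-2 stood at 2.45 ± 0.855 and 1.58 ± 0.548 CPM, and oma-2 had 3, 0 and 0 counts in A, B and C, where 0 counts allow up to 0.292 CPM in B and 1.09 CPM in C. Vitellogenins, the yolk proteins, held 0.817% ± 0.191 with 6 of 6 detected, and vit-3 stood at 1813 ± 532 CPM, although reads of vit-3, vit-4 and vit-5 may not be separable.

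The last question is how far the wild-type libraries differed, since this spread limits any comparison of alleles. The biological coefficient of variation from edgeR was 14.2%. Over 9880 genes, Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.985 for A with B, 0.984 for A with C and 0.976 for B with C. The share of genes within 1.5-fold was 90.5%, 89.7% and 82.4% for the same pairs. Chi-square per degree of freedom was 21.4, 5.76 and 14, so no pair agreed within sampling noise, as 1 library sequenced again would. Each library was counted as a separate sample. Separate preparations from 1 culture could also exceed sampling noise, so this does not show that the cultures were separate. The chi-square grows with depth and does not rank the pairs.

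Gene groups differed between libraries by more than random lists did. The median lay outside the central 95% of random lists for 10, 15 and 11 of 24 lists in A, B and C. Some lists share members, and all 8 adult-stage collagens are also cuticle collagens, so these lists are not independent. Cuticle collagens were lower in library B, with a median log2 difference of -0.68 (95% interval -0.75 to -0.61) and 128 of 131 members below the median of all genes. In A and C their differences were 0.27 and 0.41, and these rest on B: without it the values were -0.11 and 0.11. Pharynx markers at -0.44, hedgehog-related and patched-related genes at -0.37 and body wall muscle markers at -0.26 were also outside the random range in B. In C the pharynx markers were at 0.44, hedgehog-related and patched-related genes at 0.29, molting cycle genes at 0.38 and neuropeptides at 0.53, all above the random range, and without B at 0.21, 0.10, 0.31 and 0.44. Neuropeptides were at -0.58 in B and molting cycle genes, 14 of 45 of them also cuticle collagens, at -0.36, but without C these were -0.30 and -0.19. With libraries thinned to the smallest total, neuropeptides in B and C were at -0.18 and 0.26, over 18 members. Both lay inside the random ranges of the unthinned list, -0.30 to 0.095 in B and -0.054 to 0.34 in C. Only 25 of 95 neuropeptides passed the filter of at least 10 counts in every library. Rare genes pass it more easily when high in C, the shallowest library, so the neuropeptide differences are uncertain. Oogenic germline markers in B were at 0.27, and histones at 0.23, or 0.15 without A. Vitellogenins were at 0.51 in A and -0.38 in C, the latter -0.16 without A. Sperm markers, at 0.00066, 0.0054 and 0.05 in A, B and C, were inside the random range in each.

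**Figure D2:**
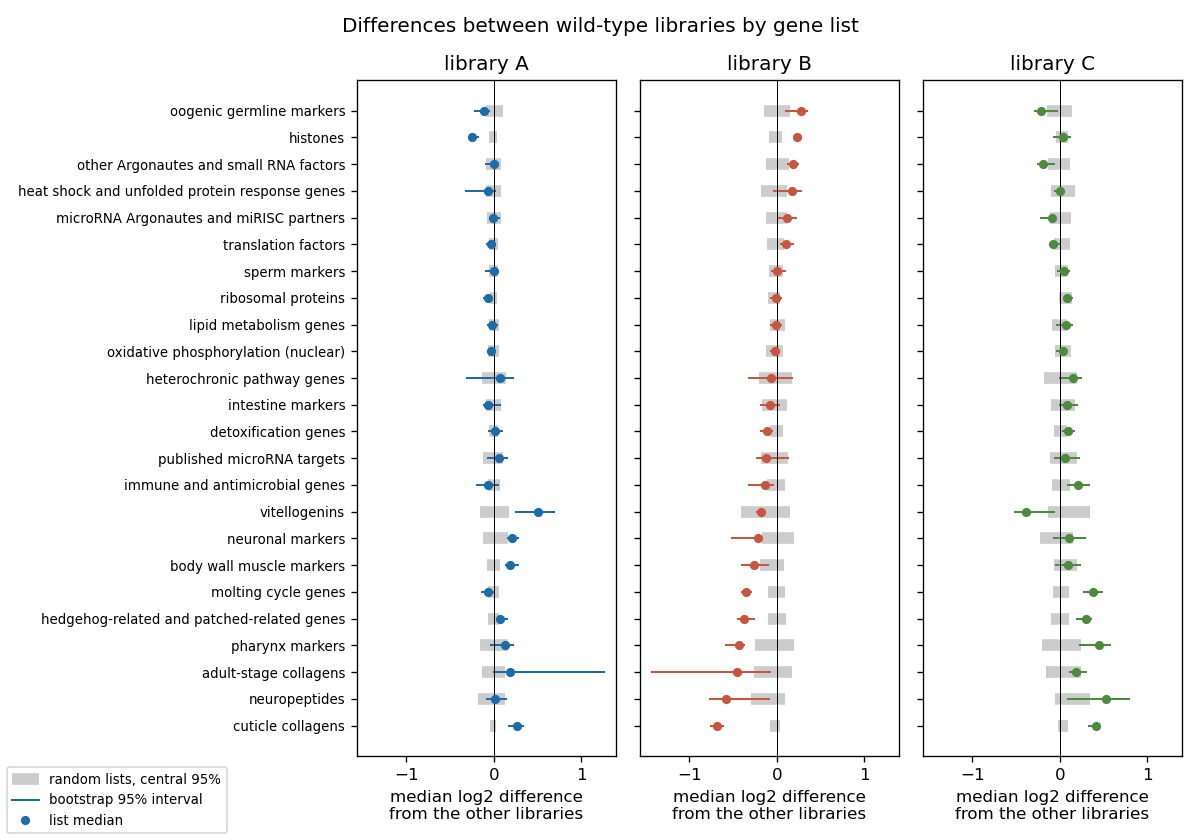
Median log2 difference of each gene list in 1 wild-type library from the other libraries, relative to all genes. Points are list medians, lines 95% intervals from resampling members and grey bars the central 95% of random lists; cuticle collagens lie at -0.68 in library B.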

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

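All alternatives were chosen after seeing the data, since those listed beforehand concern comparisons between alleles and were not run. No paired analysis was possible because no groups were compared and the library letters carry no replicate number. Leaving out 1 of 3 libraries cannot move a mean by over 1 SD, so the 387 such means of genes and 72 of list totals, none of which moved further, say nothing about stability. The coefficient of variation between wild-type libraries ranged from 11% to 16% with 1 library left out. Removing the 20 most abundant genes, which belong to some lists, moved 18 of 24 list totals by over 1 SD: body wall muscle markers to 14636 CPM, translation factors to 14744 CPM, nuclear oxidative phosphorylation to 16433 CPM and ribosomal proteins to 89694 CPM, because listed genes were removed or the total shrank. TMM scaling moved none of 129 named genes and 24 list totals beyond their spread. Its factors, 1.01, 1.04 and 0.955 in A, B and C, offset one another in a mean over libraries. These means could therefore hardly move. The 72 library differences are centred on all genes, so scaling cannot move them. Thinning moved 18 of 72 library differences (neuropeptides in B to -0.18), and at least 100 counts moved 9 of 63, with no change of sign in those outside the random range. With 1 library left out, 82 of 144 library differences moved, 5 of those outside the random range changed sign, and 57 stayed the same. The cuticle collagen differences then ranged from -0.11 to 0.62 in A, -0.73 to -0.62 in B and 0.11 to 0.73 in C. In library A, 4 further lists outside the random range changed sign: adult-stage collagens ranged from -0.00061 to 0.43, molting cycle genes from -0.31 to 0.19, hedgehog-related and patched-related genes from -0.10 to 0.28, and oogenic germline markers from -0.23 to 0.072. The cause was not tested. Depth limits rare genes most in library C, where 3 counts equal 1.09 CPM.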

Other observations

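All tests in this part were chosen after the results they concern were seen. The 12 protein-coding genes of the mitochondrial genome together had 53, 77 and 37 counts in A, B and C. This equals 8.90 ± 3.99 CPM (SD, n = 3), against 18030 ± 239 CPM for nuclear genes of oxidative phosphorylation. Whether the protocol and read processing capture footprints of mitochondrial ribosomes as well as others is not given. These totals therefore do not compare how heavily the genes were translated. Of the mitochondrial genes, atp-6 had the most, 22, 27 and 9 counts, and nduo-4 had 0 in each library. Among rows typed as pseudogene or transposable element, retr-1 stood at 301 ± 35.4 CPM and ZK546.3 at 281 ± 31.6 CPM. In the molting cycle list, mlt-11 stood at 641 ± 109 CPM. In the immune list, irg-7 stood at 1381 ± 219 CPM and the lysozyme gene ilys-5 at 1011 ± 182 CPM.

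Some genes had exactly equal counts in all 3 libraries. Among 72 histone genes, 14 of 2556 pairs were equal, such as his-10 and his-14 with 5811, 6379 and 1356 counts, where a random split of each pair's reads would give 0.00141 equal pairs. Assignment of shared reads to 1 copy at random is therefore argued against as the source of these pairs. Counting a shared read for every copy stays open. Dividing reads evenly would leave fractions unless values were then rounded, and the deposited values are whole numbers. Whether they were rounded is not given, so even division stays open on that condition only. No biological explanation was tested. Among 3593 genes with at least 100 counts in every library, 14 sets held 30 such genes: 20 histones, nspa and nspc genes, and hsp-16.48 with hsp-16.49.

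Molting cycle genes, of which 14 of 45 are cuticle collagens, were at -0.07, -0.36 and 0.38 in A, B and C, where the cuticle collagens were at 0.27, -0.68 and 0.41. The 30 other compared molting cycle genes were at -0.07, -0.33 and 0.30.

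The lower cuticle collagens of library B were weighed against 3 explanations. Thinning to 1 total left the difference at -0.70, but thinning keeps each gene's expected share, so it could hardly move abundant genes. A depth difference is argued against by the pairs of libraries. A and B had similar totals, 9121493 and 10273375 counts, yet B lay at -0.62 from A. A and C, at 9121493 and 2759428 counts, lay only 0.11 apart. A smaller share of all somatic tissue is argued against as the whole cause, since 72 pooled markers were at -0.23 (95% interval -0.34 to -0.16). This interval measures spread among markers, which are not independent of one another, and not spread between animals or cultures. Body wall muscle was at -0.26, intestine at -0.08, neurons at -0.22 and pharynx at -0.44. With thinning these were -0.28, -0.09, -0.36 and -0.42, against -0.70 for the collagens. With 1 library left out, pharynx ranged from -0.60 to -0.41 and the collagens from -0.73 to -0.62. Oogenic germline markers were at 0.27 and histones at 0.23. The third explanation was a larger share of reads in the 20 most abundant genes, which took 11.9% in B against 11.8% in A and 12.8% in C. They include the cuticle collagens col-3, col-117 and dpy-5, so these shares partly hold the difference itself. A larger share in a few genes would lower all other genes alike, and centring removes such a shift. The shares therefore decide nothing about the centred difference. Taking the 20 most abundant genes out left the difference before centring at -0.61 (-0.60 with them). With shares this close, removal could hardly move the difference, so no conclusion is drawn from it. Earlier tests of this, the median of all other genes (0.083) and the TMM-scaled difference (-0.68), were replaced after their values were seen. A smaller share of the epidermis, which makes the cuticle and had no list here, a partial shift in tissue share, and the developmental stage at harvest stay open and were not tested, and batch is not given by the labels.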
